A study of Mus musculus with 3 samples.

How the data were processed

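Tcf1 binding was measured by chromatin immunoprecipitation with an antiserum against Tcf1 in sorted CD4 T cells of Foxp3 reporter mice, per the labels' protocols. Of 3 libraries in the study, 2 entered the analysis, 1 of conventional CD4 T cells and 1 of Treg cells, each with a deposited peak list. The library of Tcf1-deficient CD4 T cells was not analysed here. The submitters' processing notes name FastQC, Bowtie2 2.3.4.1 and MACS2 2.1.1 and the mm10 build, without saying what each did. The lists are labelled by the authors as filtered, and the filter is not given in the sources used here. Each deposited list has 3 columns (chromosome, start and end) and gives no read count, height, fold or p-value, so depth is unknown and peak width took the place of a score for ranking peaks within a list. The deposited lists are per sample, and whether calling or filtering of a list also used another library is not given in the sources used here. A calling threshold that depends on depth can change the number and the width of peaks, so the lengths of the lists were not compared by a test. Minimum widths differed between the lists, at 279 bp for conventional and 240 bp for Treg.

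Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots. Coordinates are printed as 1-based positions. A peak was shared if it overlapped a peak of the other list by at least 1 bp, and belonged to 1 list alone if no peak of the other list overlapped it or had its midpoint within 1000 bp. Chance overlap came from 1000 random placements of the peaks of a list on their own chromosomes with widths kept. Shares carry exact Clopper-Pearson intervals at 95%. Widths of shared and unshared peaks were compared by a two-sided permutation test of mean ranks with 100000 resamples.

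Genes came from a RefSeq table of the mouse GRCm38.p6 assembly, whose primary chromosomes are those of mm10. It holds 49943 genes as spans, without strand, exons or introns. The plan fixed before the data were examined called for nearest transcription start sites, promoters, exons and introns. In their place a peak midpoint was assigned to every protein-coding gene it lay in, or otherwise to the nearest protein-coding gene span within 100 kb, and was placed within 1 kb of either end of any gene, elsewhere in a gene span, or between genes. With this rule 4380 conventional and 3191 Treg peaks were assigned to a gene. A search for 13 fixed sequence motifs was also planned and was not run, since no genome sequence was used here.

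Fixed before the data were examined were 13 gene lists with 320 entries for 317 distinct genes, all matched in the table by symbol. Tcf7, Lef1 and Gzmb are each in 2 lists. The number of members with a peak was compared with 10000 random lists of protein-coding genes of the same size, matched on the decile of the span of genome nearest to each gene, by a one-sided upper permutation p with Benjamini-Hochberg adjustment over 26 tests. Treg-only and conventional-only peaks near each list, and their places relative to genes, were compared by two-sided Fisher's exact tests, adjusted over 13 and 9 tests. Genes were named by a rule fixed before the data were examined. It took 10 fixed genes, the 8 widest peaks of each class (shared peaks by the sum of width ranks), and up to 4 members with the most peaks from each gene list. Values of some genes that the rule takes are not reported here. Other genes are named with a statement that they were chosen after their values were seen, or as members of a small count.

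The overlap and gene list steps were tested on simulated data. For a simulated Treg list with 40% of its peaks planted as shared with a simulated conventional list, 40.1% were recovered, with 0.187% expected by chance. Of 400 random gene lists drawn from 21887 genes, 3.25% had p under 0.05, and all of 50 lists with 15 of 30 members given a peak had p under 0.05. Simulated peaks and lists were placed without regard to gene activity, so these rates are not error rates for lists of active genes. Alternatives fixed beforehand were the wider part of each list by peak width, lists of equal length, other definitions of overlap, of gene ends and of gene assignment, merging of peaks within 1000 bp, and random moves of peaks by 20 to 200 kb.

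Alternatives added after seeing the data left out Lef1, chromosomes X and Y, or dense arrays of peaks, or kept the shared and unshared classes of the full lists in the wider part of each list and at equal lengths. In the alternatives fixed beforehand, classes were found anew in the reduced lists, so a peak whose partner was removed counted as unshared. An array was a run of peaks with neighbouring midpoints at most 20 kb apart that held at least 10 peaks of 1 list. A limit of 10 kb was tried before, and it was widened after its result for chromosome Y had been seen, so results that rest on arrays are given under both limits. The limit of 20 kb gave 6 arrays with 31 conventional and 105 Treg peaks, and the limit of 10 kb gave 5 arrays with 31 and 85. With 20 kb, an array on chromosome 8 (123540397 to 123624140) held 18 Treg and 0 conventional peaks over 47 ribosomal RNA genes. Another on chromosome 6 overlapped Rn4.5s and held 18 Treg and 8 conventional peaks.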

Results

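Binding of Tcf1, the HMG-box transcription factor encoded by Tcf7, was mapped by chromatin immunoprecipitation and sequencing in CD4 T cells sorted from mouse spleen. Conventional CD4 T cells lacked CD25 and the Foxp3 reporter, and regulatory T cells (Treg cells) carried both. The title and source of the conventional sample call it conventional while its tissue label calls it effector, and it is called conventional throughout. Each cell type was represented by 1 library and 1 peak list on the mm10 build. A Tcf1-deficient CD4 T cell library of the same study was not analysed here, and whether it served as the control in peak calling is not given in the sources used here. The conventional list held 4519 peaks with a median width of 428 bp (interquartile range 347 to 557 bp) that covered 2.18 Mb. The Treg list held 3402 peaks with a median width of 366 bp (295 to 472 bp) that covered 1.44 Mb. Both lists spanned 21 chromosomes. The lists give positions without read counts, so the sequencing depth behind them is unknown. With no replicates, every test below compares 2 peak lists and not 2 cell types, and the 95% Clopper-Pearson intervals cover counting error only.

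The first question was which loci carried Tcf1 peaks in both cell types. Tcf1 peaks lay at the genes for Tcf1 itself and for its close relative Lef1 in both lists. Tcf7 (chromosome 11, 52246527 to 52283383) had 7 conventional and 7 Treg peaks, of which 6 were shared. The widest of them in the conventional list (52313680 to 52314865) lay 30890 bp outside the gene span, and another (52282867 to 52283803) lay at the gene's end. Lef1 (chromosome 3, 131110297 to 131224357) had 10 conventional peaks, 4 of them shared and 6 found in the conventional list alone, and 5 Treg peaks, 4 of them shared. The other Treg peak at Lef1 had its midpoint within 1000 bp of that of a conventional peak, so none was Treg-only. Axin2, a negative regulator and target of Wnt signalling, had 3 peaks in each list, all 3 shared, and the one inside the gene (chromosome 11, 108920073 to 108921575 in the conventional list) was 1503 bp wide. Within the gene span and 10 kb around it, Tcf7 had 4 peaks in each list, Lef1 had 8 conventional and 4 Treg peaks, and Axin2 had 2 in each list.

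**Figure D1:**
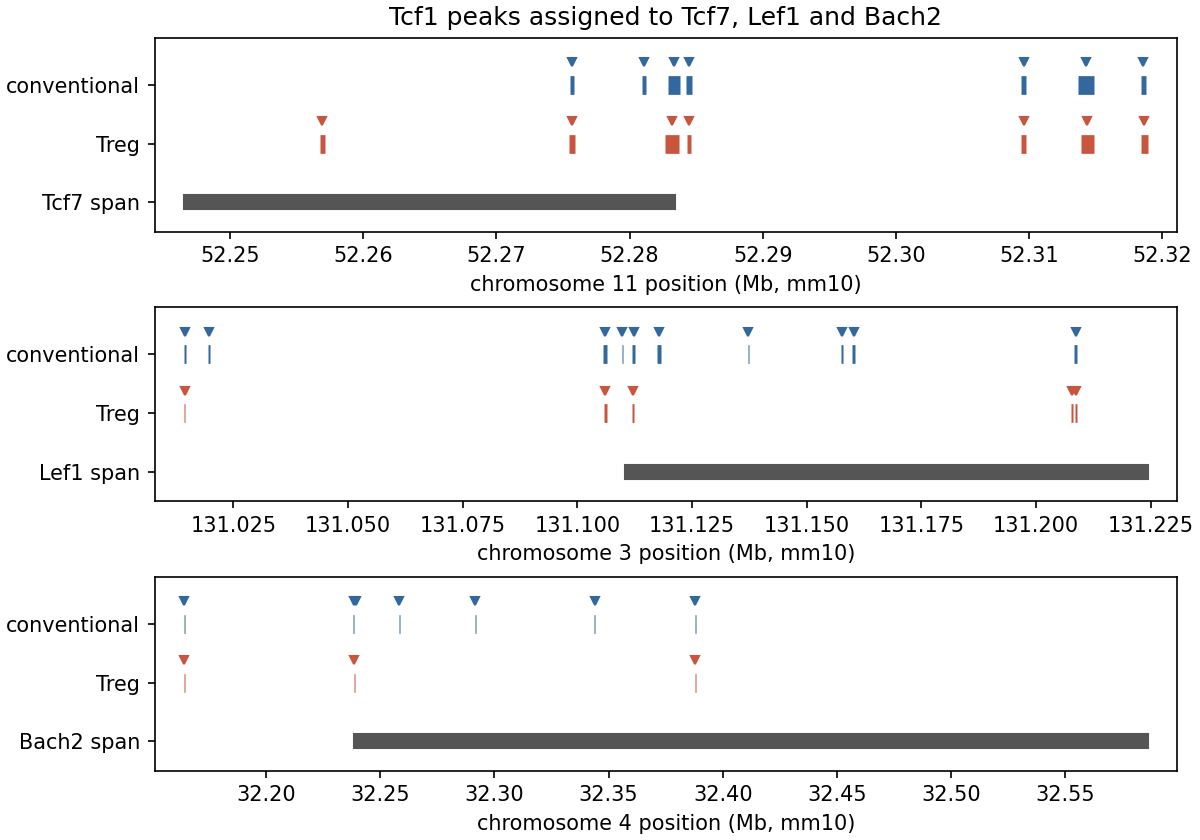
Tcf1 peaks assigned to Tcf7, Lef1 and Bach2, plotted by chromosome position in Mb (mm10), with conventional peaks in blue, Treg peaks in red, a triangle above each peak midpoint and the gene span in grey. Tcf7 has 7 peaks in each list, Lef1 has 10 conventional and 5 Treg peaks, and Bach2 has 7 conventional and 3 Treg peaks.

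Among genes that mark Treg cells, Il2ra (the CD25 chain of the interleukin 2 receptor) had 1 shared peak inside the gene, at chromosome 2, 11653255 to 11653853 in the conventional list. Ctla4, an inhibitory receptor, had 1 shared peak at its gene end on chromosome 1 (60908888 to 60909237 in the conventional list). No peak was assigned to Foxp3, the lineage factor of Treg cells, or to Cd4 in either list. Ikzf2, which encodes Helios, had 1 peak in the conventional list and 0 in the Treg list. Bcl6, the regulator of follicular helper T cells, had 1 shared peak at its gene end and 1 unshared peak in each list. Bach2, a repressor that keeps T cells from effector differentiation, had 7 conventional peaks and 3 Treg peaks (6 and 2 within 10 kb of the gene span), and the 3 Treg peaks were all shared.

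Over the whole lists, 1934 of 4519 conventional peaks overlapped a Treg peak by at least 1 bp, or 42.8% (95% interval 41.3% to 44.3%). In the other direction 1935 of 3402 Treg peaks overlapped a conventional peak, or 56.9% (55.2% to 58.6%). Random placement of the peaks on their own chromosomes gave a mean of 0.13% for the conventional list and 0.171% for the Treg list, and no placement exceeded 0.288% or 0.441% (one-sided permutation p = 0.001 in both directions, the smallest that 1000 placements can give). These placements did not keep the distance of peaks to genes, and both lists were concentrated near gene ends. The contrast therefore does not tell shared binding from background peaks that recur in both lists. A further 58 conventional and 60 Treg peaks lay close to a peak of the other list without a match by overlap. The remaining 2527 conventional-only and 1407 Treg-only peaks had neither an overlap nor a midpoint of the other list within 1000 bp.

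Shared peaks were the wider peaks of each list. Their median width was 497 bp against 387 bp for unshared peaks in the conventional list, a difference of 110 bp, and 408 bp against 322 bp in the Treg list, a difference of 86 bp (two-sided permutation p = 1e-05 in each list, the smallest that 100000 resamples can give). By quintile of width, the shared share of conventional peaks went from 21.9% (19.2% to 24.7%) among the narrowest to 65.9% (62.7% to 69.0%) among the widest. In the Treg list it went from 33.0% (29.5% to 36.7%) to 82.1% (79.0% to 84.9%). Across the 1935 shared Treg peaks and their conventional partners, midpoints lay a median of 59 bp apart and widths correlated with Pearson r = 0.52 and Spearman rho = 0.37 (permutation p = 1e-05 for both, the smallest possible). Without the 2 pairs farthest from the median width, Pearson r was 0.40 and Spearman rho was 0.37. Peaks are not independent replicates, and these correlations describe 1 library of each cell type.

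**Figure D2:**
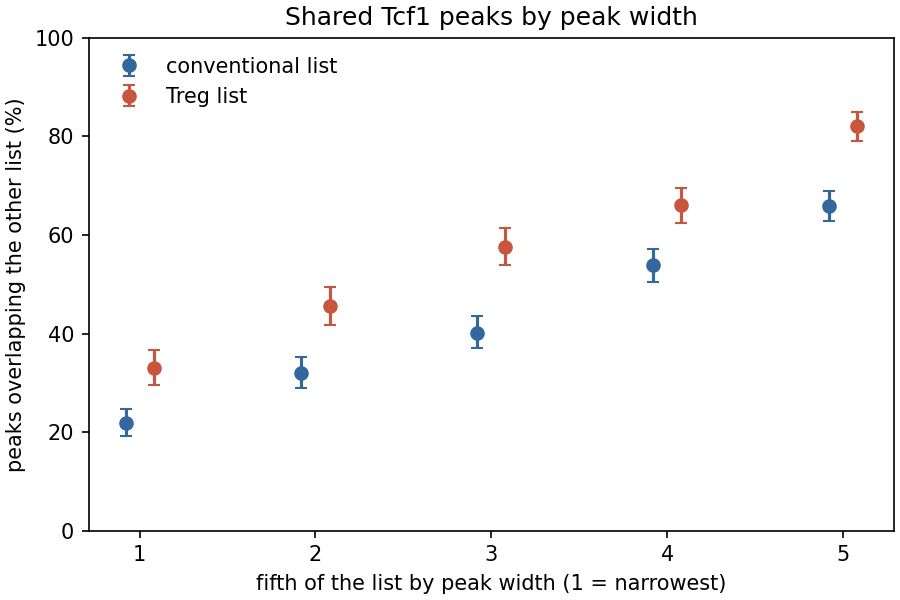
Share of Tcf1 peaks (%) that overlap a peak of the other list, by quintile of peak width from the narrowest (1) to the widest (5), for the conventional list (blue) and the Treg list (red), with 95% Clopper-Pearson intervals. The share rises from 21.9% to 65.9% in the conventional list and from 33.0% to 82.1% in the Treg list.

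The next comparison was between the genes near the peaks. Of 21887 protein-coding genes, 3561 had a conventional peak and 2691 a Treg peak assigned to them, and 1788 had both. Random assignment that kept the span of genome nearest to each gene gave a mean of 466 genes in common and at most 547 (one-sided permutation p = 1e-04, the smallest that 10000 random draws can give). Shared peaks mostly fall to the same gene, so this overlap follows in part from the sharing of peaks and is not separate support for it. The random draws were not matched on expression. A conventional peak without a Treg peak was assigned to 1773 genes, and the reverse to 903 genes. Midpoints of overlapping peaks can be assigned to different genes, so some genes in these counts carried a shared peak.

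Genes of naive and memory T cells were the list with the largest share of members carrying a conventional peak among the 13 lists tested. A conventional peak was present at 21 of 24 members, against 4.45 in matched random lists (adjusted permutation p = 0.00037), and a Treg peak at 16 of 24, against 3.64 (adjusted permutation p = 0.00037). All 16 also had a conventional peak. Besides Lef1, Tcf7 and Bach2 the list included Ccr7, the lymph node homing receptor, with 5 conventional and 2 Treg peaks (3 and 1 within 10 kb of the gene span). Its peak inside the gene (chromosome 11, 99146942 to 99148300), 1359 bp wide, was among the 8 widest conventional-only peaks. S1pr1, the receptor that directs exit from lymphoid organs, had 3 conventional-only peaks and no Treg peak. S1pr1 was picked out after its values were seen. Adjusted p-values are Benjamini-Hochberg values over 26 one-sided tests, and 0.00037 is the smallest adjusted value reached. Random lists were drawn from all protein-coding genes and were not matched on expression. For every list below, the test therefore cannot tell a preference for that list from one for genes active in T cells.

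Genes of T cell receptor signalling carried peaks at 20 of 29 members in each list, 17 of them the same, against 5.12 conventional and 4.12 Treg members in matched random lists (adjusted permutation p = 0.00037 for both). Zap70, the kinase recruited to the activated receptor, had 3 conventional and 2 Treg peaks, and the adhesion receptor Cd2 and the inhibitory receptor Cd5 had 2 in each list. Both Cd5 peaks were shared, while Cd2 shared 1 of its 2. Within 10 kb of the spans, Cd5 had 1 peak in each list and Cd2 had 1 conventional and 2 Treg peaks. Activation transcription factors carried a peak at 19 of 26 members in the conventional list and 18 in the Treg list, 15 of them the same (4.68 and 3.51 by chance, adjusted permutation p = 0.00037 for both). Examples were Nr4a1, an immediate early gene of receptor stimulation, with 5 conventional and 3 Treg peaks, and Fos and Junb, subunits of AP-1, with 3 and 4 conventional and 4 and 3 Treg peaks. Within 10 kb of the Fos span lay 1 peak of each list. Nfkbia, the inhibitor of NF-kappaB, had 3 conventional and 2 Treg peaks (2 and 1 within 10 kb of its span).

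Wnt pathway targets and regulators carried a conventional peak at 18 of 31 members (5.70 by chance, adjusted permutation p = 0.00037) and a Treg peak at 13 of 31 (4.78 by chance, adjusted permutation p = 0.00095). All 13 also carried a conventional peak. Znrf3, a ubiquitin ligase that removes Wnt receptors, had 4 conventional peaks and 2 Treg peaks, both shared. Helper lineage regulators and cytokines carried a peak at 14 of 32 members in each list, 13 of them the same (5.66 by chance and adjusted permutation p = 0.0015 for conventional, 4.53 and 0.00078 for Treg). Runx1, a transcription factor of T cell development, had 5 conventional and 3 Treg peaks. Runx3, a related factor that represses Cd4, had 3 conventional and 2 Treg peaks (2 and 1 within 10 kb), and Il21, a follicular helper cytokine, had 2 conventional and 1 Treg peak, none of them within 10 kb of its span. No peak in either list was assigned to Tbx21 or Gata3, the lineage factors of Th1 and Th2 cells. Both genes were picked out after their values were seen.

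Treg signature genes carried a conventional peak at 14 of 34 members (5.97 by chance, adjusted permutation p = 0.0024) and a Treg peak at 13 of 34 (4.56 by chance, adjusted permutation p = 0.00065). A peak in both lists was found at 10 members, among them Prdm1 (which encodes Blimp-1) with 3 conventional and 2 Treg peaks, and Ikzf4, Tigit and Ccr8. Ikzf4, which encodes Eos, and the inhibitory receptor Tigit each had 1 Treg-only peak beside a shared peak, the Ikzf4 peak inside the gene at chromosome 10, 128645688 to 128646476, and the Tigit peak 44264 bp outside the gene, which left 1 Treg peak within 10 kb of the Tigit span. A Treg peak without a conventional peak was found at Il2rb, Tnfrsf9 and Il10, and the reverse at Ikzf2, Capg, Rgs1 and Gzmb. Among the widest conventional peaks (2259 of the list), 6 members remained with a peak and the conventional result did not pass the threshold (adjusted permutation p = 0.17, range over the alternatives 0.002 to 0.17).

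Cell cycle genes carried a conventional peak at 13 of 27 members (4.31 by chance, adjusted permutation p = 0.00078) and a Treg peak at 6 of 27 (3.16 by chance, adjusted permutation p = 0.14). The 6 members with a Treg peak were Ccnd2, Ccnd3, Cdk4, Cdkn1a, Cdkn1b and Rb1, and each of them also had a conventional peak. Ccnd3 had 4 conventional and 3 Treg peaks, and 5 in each list when all peaks within its span and 10 kb around it were counted. Cdkn1b, which encodes the cell cycle inhibitor p27, had 1 conventional-only and 2 Treg-only peaks. In the 1701 widest Treg peaks 5 members had a peak and the list passed the threshold (adjusted permutation p = 0.045, range over the alternatives 0.045 to 0.14). Housekeeping genes, fixed as a comparison list, carried a conventional peak at 8 of 22 members (3.07 by chance, adjusted permutation p = 0.0095) and a Treg peak at 7 of 22 (2.17 by chance, adjusted permutation p = 0.0071). The comparison list thus passed the threshold in both peak lists, as the naive and memory, T cell receptor, helper lineage and Treg signature lists did. Ywhaz had 3 peaks in each list, all shared, Actb had 2 conventional peaks and 1 Treg peak, and Ppia had 1 shared peak. With the lists at equal lengths the conventional housekeeping count was 6 (adjusted permutation p = 0.052, range 0.0082 to 0.052).

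Lists for other cell types did not pass the test in either cell type. CD8 and cytotoxic T cell genes had a conventional peak at 4 of 18 members (adjusted permutation p = 0.43) and a Treg peak at 1 of 18 (adjusted permutation p = 1). Of that list Fasl had 7 conventional peaks and 2 Treg peaks, both shared, of which 2 conventional and 0 Treg peaks lay within 10 kb of its span, while Gzmb, Cd8b1 and Xcl1 had peaks in the conventional list alone. No peak lay within 10 kb of the Gzmb or Xcl1 span. B cell genes had a conventional peak at 1 of 18 members (adjusted permutation p = 1) and a Treg peak at 2 (adjusted permutation p = 0.89), with a shared peak at Pou2af1 and a Treg-only peak 64852 bp from Cr2. Myeloid genes had a conventional peak at 3 of 20 members, Fcgr3, Tyrobp and Cebpb, and a Treg peak at 2, Fcgr3 and Tyrobp (adjusted permutation p = 0.89 for both). When all peaks within 10 kb of a span were counted, Cr2 and Cebpb had 0, Fcgr3 had 1 conventional and 0 Treg peaks, and Tyrobp had 2 conventional peaks and 1 Treg peak. None of the 19 liver genes had a peak in either list (adjusted permutation p = 1 for both), and of the 20 neuron genes Dlg4 alone had peaks (adjusted permutation p = 1 for both).

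**Figure D3:**
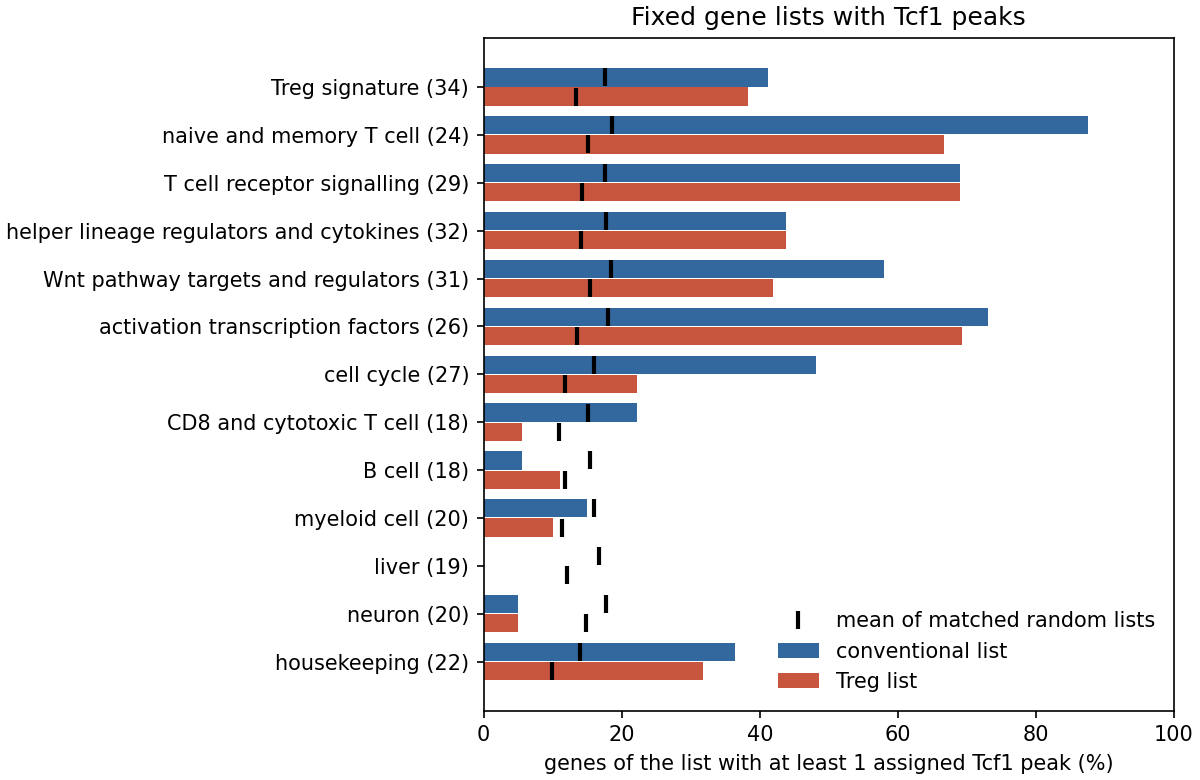
Genes of each fixed list (number of genes in brackets) with at least 1 assigned Tcf1 peak, in percent, for the conventional list (blue bars) and the Treg list (red bars), with black ticks for the mean of 10000 matched random lists. The naive and memory T cell list stands highest in the conventional list, at 21 of 24 genes, and no bar is drawn for the liver list, which has 0 of 19.

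Peaks found in 1 list alone were then compared by the genes near them. Wnt pathway genes were near 19 of 2527 conventional-only peaks (0.752%) and 1 of 1407 Treg-only peaks (0.0711%), a difference of -0.681 percentage points (two-sided Fisher's exact p = 0.0036, adjusted p = 0.047 over 13 lists). Of the conventional-only peaks 6 were at Lef1, and without Lef1 the difference was -0.443 points (adjusted Fisher p = 0.20). With a 20 kb limit on distance it was -0.602 points (adjusted Fisher p = 0.072). With classes found anew in the reduced lists, as planned, it was -0.469 points at equal list lengths (adjusted Fisher p = 0.70) and changed sign among the widest peaks (+0.0297 points, adjusted Fisher p = 1), where peaks that lost their partner counted as unshared. With the classes of the full lists, an alternative chosen after seeing the data, it was -0.636 points (adjusted Fisher p = 0.12) and -0.724 points (adjusted Fisher p = 0.38). No other list differed after adjustment. Naive and memory T cell genes were near 29 conventional-only and 6 Treg-only peaks (Fisher's exact p = 0.021, adjusted p = 0.14), CD8 and cytotoxic genes near 9 and 0 (p = 0.031, adjusted p = 0.14), and Treg signature genes near 6 and 5 (p = 0.54, adjusted p = 0.78). For CD8 and cytotoxic genes the counts fell to 3 and 0 within 10 kb of the spans (Fisher's exact p = 0.56). With the nearest gene within 20 kb they were 4 and 0 (Fisher's exact p = 0.3). Among the widest peaks, with classes found anew, Treg signature genes were near 7 of 771 Treg-only peaks (0.908%) and 1 of 1336 conventional-only peaks (0.0749%; Fisher's exact p = 0.0047, adjusted p = 0.061). With the classes of the full lists they were near 3 of 456 (0.658%) and 1 of 967 (0.103%; Fisher's exact p = 0.10, adjusted p = 0.38).

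The last comparison was the place of the peaks relative to annotated genes. Treg-only peaks lay near gene ends less often, and between genes more often, than either conventional-only or shared peaks. Within 1 kb of a gene end were 39.0% (36.5% to 41.6%) of Treg-only peaks, 53.8% (51.8% to 55.7%) of conventional-only peaks and 54.6% (52.4% to 56.9%) of shared peaks of the Treg list. Intergenic peaks made up 27.1% (24.8% to 29.5%), 14.0% (12.6% to 15.4%) and 15.4% (13.8% to 17.1%) of these classes. Treg-only and conventional-only peaks differed by -14.8 percentage points near gene ends (adjusted Fisher p = 1.7e-18 over 9 tests) and by 13.1 points between genes (adjusted Fisher p = 2.5e-22), and not past the threshold elsewhere in gene spans (1.65 points, adjusted Fisher p = 0.34). Treg-only and shared peaks differed by -15.6 points near gene ends (adjusted Fisher p = 1.7e-18), 11.7 points between genes (adjusted Fisher p = 4.3e-16) and 3.93 points elsewhere in gene spans (adjusted Fisher p = 0.032). Conventional-only and shared peaks did not differ past the threshold in any of these places (adjusted Fisher p = 0.54, 0.24 and 0.14).

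Every class lay near gene ends more often than randomly placed peaks did. Over all peaks the shares near a gene end were 54.3% (52.9% to 55.8%) in the conventional list and 48.2% (46.5% to 49.9%) in the Treg list, against means of 6.54% and 6.37% over 50 random placements. Among the widest peaks the difference between Treg-only and conventional-only peaks near gene ends was -15.6 percentage points with the classes of the full lists, and -8.70 points when peaks that lost their partner to the width limit counted as unshared. Gene starts and gene ends could not be told apart, since the gene table used here gives no strand.

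**Figure D4:**
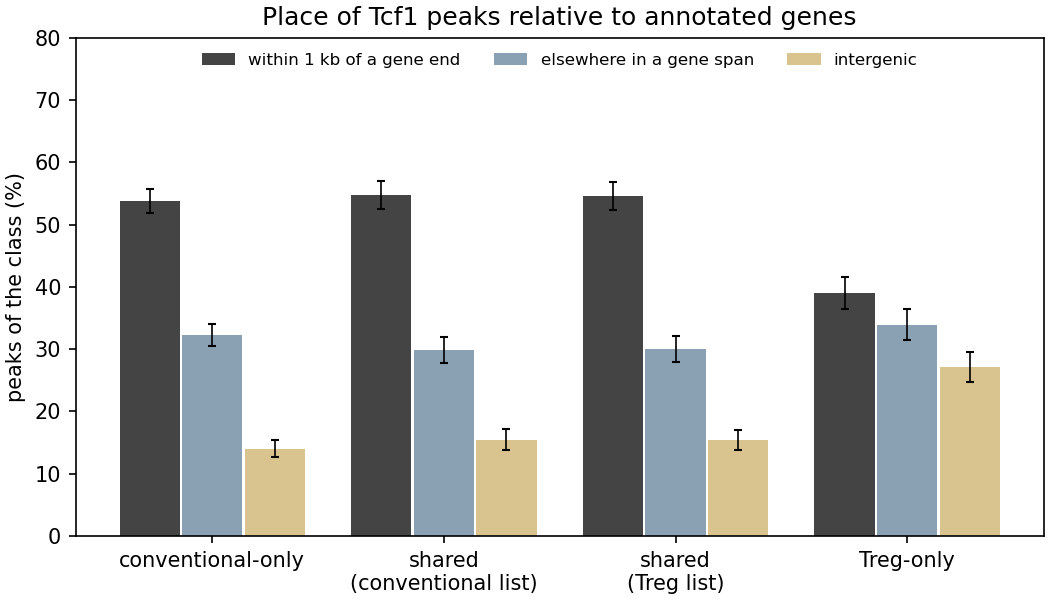
Share of Tcf1 peaks (%) within 1 kb of a gene end (dark grey), elsewhere in a gene span (blue) and intergenic (tan), for conventional-only peaks, shared peaks of each list and Treg-only peaks, with 95% Clopper-Pearson intervals. Treg-only peaks have the lowest share near gene ends, 39.0%, and the highest intergenic share, 27.1%.

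The widest peaks of each class were named by rule. Of the 8 shared peaks with the highest combined width ranks, the widest (chromosome 17, 39843016 to 39848817 in the Treg list) overlapped Rn18s-rs5, annotated as a pseudogene related to 18S ribosomal RNA. Whether that peak reflects Tcf1 binding was not tested. Others of the 8 lay inside Axin2 and inside Hivep1 (chromosome 13, 42051586 to 42052982), a zinc finger gene. Another lay nearest to Tex44, and 4 lay in dense arrays of peaks on chromosomes 6, X and Y. The 8 widest conventional-only peaks included peaks at Ccr7, Hnrnpf, Bclaf1, Kmt5b, Smad4 and Rbm39, a peak nearest to Smndc1, and 1 in the noncoding gene Gm26901, and 0 of them lay in an array. Smad4, the common mediator of TGF-beta signalling, carried its peak at chromosome 18, 73703037 to 73704243. Of the 8 widest Treg-only peaks 4 lay in the arrays of chromosomes X and Y. The other 4 lay in 2700054A10Rik (chromosome 17, 13550722 to 13553139), in Stam2 (chromosome 2, 52696525 to 52697992), and nearest to Zfp825 and Tmem125.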

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

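Of the alternatives to the results that answer a comparison, 43 counted as unchanged, 8 moved a value with no test, 5 lost a call and 1 reversed. Unchanged meant the same direction and side of the threshold, a share within the interval, or a count changed by no more than a set ratio. Of those for gene lists and named genes, 194 kept the call or changed a count by no more than that ratio, 2 lost a call and 1 gained a call. A further 23 moved, all 23 by assigning to a gene the peaks in its span and 10 kb around it. Leaving out Lef1, chromosomes X and Y or dense arrays, keeping the classes of the full lists, and the random moves of peaks for the conventional list, were chosen after seeing the data. The sharing of peaks stayed far above random placement under each alternative tried, from 35.4% to 49.1% for conventional and from 47.1% to 58.6% for Treg peaks. No placement was matched on distance to genes. The lower share of Treg-only than conventional-only peaks near gene ends kept its direction and its call in the 7 alternatives run, from -16.4 to -8.70 percentage points. The difference in Wnt pathway genes between Treg-only and conventional-only peaks was lost at equal list lengths (-0.469 points, adjusted Fisher p = 0.70, and -0.636 points, 0.12, with the classes of the full lists), with the nearest gene within 20 kb (-0.602 points, adjusted Fisher p = 0.072) and without Lef1 (-0.443 points, adjusted Fisher p = 0.20), and it reversed among the widest peaks of each list (+0.0297 points, adjusted Fisher p = 1). The reversal came from peaks that lost their partner to the width limit, since with the classes of the full lists the difference was -0.724 points (adjusted Fisher p = 0.38). What ended the call without Lef1 and within 20 kb was not tested beyond the fewer peaks counted. Keeping the wider part of each list left 2259 conventional and 1701 Treg peaks by construction, and put 57.2% and 52.9% of them near gene ends. Over the full lists the shares near gene ends were 54.3% and 48.2%. A distance of 2.5 kb in place of 1 kb raised these full-list shares to 64.4% and 57.8% by construction, and protein-coding genes alone lowered them to 48.1% and 41.8%. The alternatives for motifs in peaks were not run, as no genome sequence was used here. No replicate could be left out and no samples could be split in other ways, with 1 library of each cell type. No paired analysis was possible because each cell type has 1 library. Depth is unknown, so how far it limits the shorter Treg list was not measured.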

Other observations

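Genes outside the fixed lists carried some of the densest groups of Tcf1 peaks, and they were picked out after their values were seen. Chd2, which encodes a chromatin remodeller, had 7 conventional and 6 Treg peaks, with 5 of each shared. Fli1, an ETS family transcription factor, and Scml4, a Polycomb family gene, each had 6 conventional and 4 Treg peaks, and their 4 Treg peaks were all shared. Itpkb, an inositol kinase needed for T cell development, had 6 conventional and 5 Treg peaks, of which 2 were shared. Prkch, a protein kinase C gene, had 7 conventional peaks and 3 Treg peaks, all 3 shared. A run of 5 conventional and 4 Treg peaks lay at the constant region of the T cell receptor alpha chain (chromosome 14, 54222281 to 54234027). Another with 6 conventional and 5 Treg peaks lay at Junb and Hook2 (chromosome 8, 84975987 to 84990572).

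The tests of arrays, of sex and of the share of Treg signature peaks below were chosen or reworded only after the result was seen, and the others before.

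Fewer than 60% of either list was shared. At equal lengths 49.3% of Treg and 49.1% of conventional peaks were shared, which decides nothing about the lengths of the lists, because shortening a list can only remove partners and neither share could have reached 60%. Weaker peaks near the calling threshold remain a candidate explanation, with width in place of strength, because the shared share was 2.48 times higher in the widest than in the narrowest quintile of the Treg list and 3.01 times higher in the conventional list. The shares among the widest peaks of both lists alone, 53.6% of Treg and 40.3% of conventional peaks, decide nothing here either, since that limit also removes partners from the other list. Binding that differs between the cell types stays open and untested, since no replicate shows how much of a list comes back in a repeat of the same cell type.

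Chromosomes X and Y took a larger share of the Treg list, with 86 of 3402 peaks (2.53%) against 49 of 4519 (1.08%) on X (Fisher's exact p = 1.1e-06) and 26 (0.764%) against 8 (0.177%) on Y (Fisher's exact p = 8.6e-05). Copies of the Foxp3 region carried by the reporter do not account for X, since both cell types were sorted from reporter mice. In addition, 1 of 59 Treg-only X peaks lay within 200 kb of Foxp3. Without the arrays at Mid1 and Erdr1 and elsewhere X still differed (Fisher's exact p = 0.00034 with a 20 kb limit, 0.00035 with 10 kb). On Y the answer depends on the limit, and the wider one was set after the narrower one had been seen. With 20 kb, 1 Treg and 0 conventional peaks stay on Y (Fisher's exact p = 0.42), and with 10 kb 4 and 0 (p = 0.033), so these tests do not decide whether arrays account for Y. A different sex of the animals would move X and Y in opposite directions. The Y array of the 20 kb limit held all 8 conventional and 25 of the 26 Treg peaks on Y, so the Y difference came from 1 stretch of the chromosome. The Fisher tests counted such neighbouring peaks as independent. Too few Y peaks lay outside the arrays under either limit to decide on sex, which may still contribute.

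Treg-only peaks lay near gene ends less often than conventional-only peaks. Arrays do not account for this, since without them the difference was -15.1 percentage points (Fisher's exact p = 4.8e-19) and with the 10 kb limit -15.0. Background peaks among the Treg-only peaks could contribute and cannot be told apart from binding. The widest tertile lay near gene ends 5.06 points more often than the narrowest (43.0% against 37.9%, Fisher's exact p = 0.13). Near gene ends lay 39.0% of Treg-only peaks against 6.37% of random placements. Those placements were uniform along chromosomes and background peaks need not be, so this contrast decides nothing about background. Peaks at the fixed Treg signature genes, distal or not, were too few to make up the difference, at 0.373% of Treg-only peaks outside the arrays (upper limit 0.869%). That bound was set after the test written beforehand, Treg-only against conventional-only peaks, had left the question open (0.136 points, Fisher's exact p = 0.53). With 34 genes in the list such a share was bound to be small, so the bound decides nothing about distal binding in Treg cells. Distal binding at other genes of Treg cells stays open and untested.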
